A study of Mus musculus with 12 samples.

How the data were processed

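Total RNA, 100 ng per sample, from wild-type and MLL1 knockout mouse embryonic fibroblasts was hybridised to 12 Affymetrix arrays, 3 for each genotype and time. Per the labels' protocols, cells grown in medium with 5% fetal bovine serum and 5% newborn calf serum received a shock of 50% horse serum for 2 h and were sampled at 18 h and 30 h. The deposited values are intensity per probe set on a linear scale, made with Affymetrix Expression Console 1.1 and PLIER 2.0, per the submitters' processing notes. Which normalization between arrays the authors ran within PLIER is not given in the sources used here. The table holds 35557 probe sets, of which 21789 have 1 gene symbol in the platform annotation, 1621 have several and 12147 have none listed. Of those with 1 symbol, 21698 were matched by Entrez number to a RefSeq gene table of assembly GRCm38.p6, used for names and for the order of neighbouring genes.

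Groups were taken from the sample labels. Values were taken as log2(intensity + 16), so fold changes are on that scale, which understates the change of dim genes. Each gene was represented by its probe set of highest mean, which gave 19938 genes, and the 13956 genes with a mean at or above the 30th percentile (log2 7.58, an intensity of about 175) were tested. Of 904 tested genes with several probe sets, 160 had probe sets of opposite sign in the averaged knockout effect and 10 had probe sets called in opposite directions. The 4 group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with 8 residual and 7.98 prior degrees of freedom. All adjusted p-values are limma's two-sided moderated tests with Benjamini-Hochberg adjustment over the genes tested in a comparison, called under 0.05. The comparisons were knockout against wild type at each time and averaged over both, 30 h against 18 h in each genotype, and the difference of the time effects. The number of arrays limits the precision.

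Gene lists, 41 in all and 40 with at least 4 tested members, were tested with camera at a preset correlation of 0.01, with p-values adjusted over the lists of a comparison. An estimated correlation and the rotation test fry were alternatives. Of the lists called with the preset correlation, 1 of 17 held with an estimated correlation for knockout at 18 h, 1 of 14 at 30 h, 2 of 16 for time in wild type, 0 of 9 for time in knockout and 2 of 13 for the difference of time effects.

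The genes named in the text followed a rule. For each comparison these were Kmt2a, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap in any array (no such condition for the difference of time effects), with predicted genes passed over. The tested core clock genes with Dbp, Tef, Hlf and Nfil3 were added for the time comparisons, and up to 2 rises and 2 falls for each gene list that was called or had at least 2 called members. The list was then shortened, keeping the former kinds first. The groups, the tests of the comparisons, the gene lists, the naming rule and the alternatives were fixed before the data were examined. Gene-by-gene array weights and tests of 2 technical explanations, a wrong time label and blood cells, were added after.

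The alternatives were offsets of 1 and 64, no filter and a filter at the 50th percentile, quantile, median and cyclic loess scaling, no intensity trend, robust eBayes, array weights, only the arrays of the groups compared, the mean of all probe sets of a gene, all probe sets, a 2-fold change in addition, the replicate number as a block, and each array left out in turn. The fits were tested on simulated data for 13956 genes. With 100 genes changed by 1 on the log2 scale, 100, 99 and 99 were recovered for knockout at 18 h, at 30 h and averaged, 98 and 99 for time in wild type and knockout, and 88 for the difference of time effects. With 100 genes changed by 0.5, the numbers recovered were 72, 71, 90, 71, 68 and 38 in the same order. The share of false calls was between 3.08% and 6.18%. The simulated noise was independent between genes and arrays and few genes were changed, so this share need not hold for the real calls.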

Results

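RNA from mouse embryonic fibroblasts, connective tissue cells grown from embryos, was measured on 12 Affymetrix gene expression arrays. The cells were wild type or labelled knockout for MLL1, a histone methyltransferase encoded by Kmt2a. Each genotype was sampled 18 h and 30 h after a serum shock, a 2 h pulse of 50% horse serum that aligns the circadian clocks of cultured cells. Each of the 4 groups holds 3 arrays. The design asks how gene expression differs between the genotypes at 2 circadian times. The number of arrays limits the precision of every value, and nothing in the labels says that the replicates are separate cultures, so p-values measure the spread between these arrays, which may be technical.

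The median intensity of the arrays ran from 273.3 to 311.8. Arrays of the same group correlated at 0.984 to 0.996 across the tested genes, and arrays of different genotypes at 0.771 to 0.831. The median replicate SD of a gene was between 0.0814 and 0.106 on the log2 scale in the 4 groups. The first principal component separated the genotypes and held 86.8% of the variance, and the second, with 7.11%, separated the times. On the second component, knockout 18 h replicates 2 and 3 lay at -25.2 and -24.9 and the knockout 30 h arrays at 20.0 to 24.6, while knockout 18 h replicate 1 lay between them at -9.34.

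**Figure D1:**
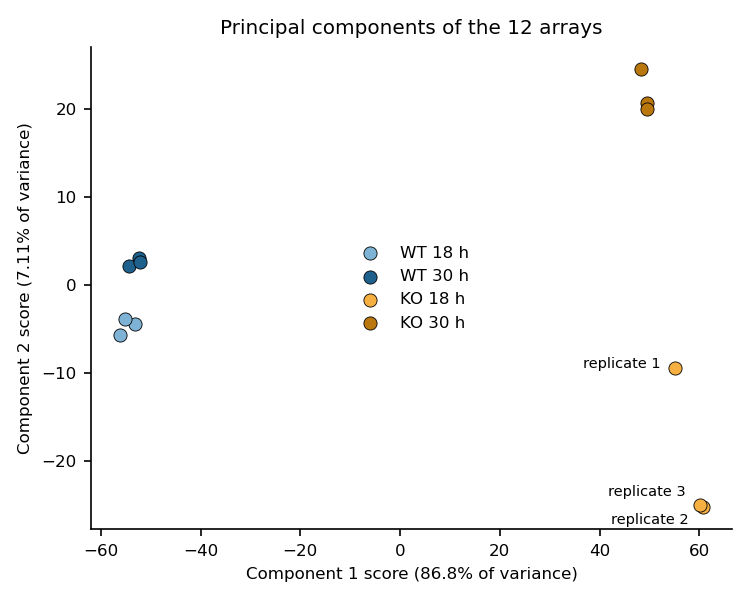
Scores of the 12 arrays on the first (x axis, 86.8% of variance) and second (y axis, 7.11%) principal components of log2 intensity, 1 point per array, coloured by group. The genotypes part along the x axis, and knockout 18 h replicate 1 at -9.34 on the y axis lies apart from replicates 2 and 3.

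Kmt2a was measured first, since it is the targeted gene. In wild type its intensity was 2265, 2824 and 2100 at 18 h and 2129, 2155 and 2069 at 30 h. In the arrays labelled knockout it was 2120, 2174 and 1960 at 18 h and 1338, 1367 and 1584 at 30 h. The log2 difference at 18 h was -0.19 (adjusted p = 0.108), and it became -0.28 (adjusted p = 0.0235) without wild-type 18 h replicate 3 and -0.07 (adjusted p = 0.565) without wild-type 18 h replicate 2. At 30 h Kmt2a was lower in knockout by a log2 difference of -0.57 (adjusted p = 0.000111). The labels do not say which part of the gene was disrupted or where the probes lie relative to it, so these values do not check the genotype labels.

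At 18 h interferon-stimulated genes and many HOX genes, which encode transcription factors of body position, were lower in the knockout cells than in wild type. Whether differences between the genotypes follow from the targeted gene or from the history of the cells was not tested. The labels name no separate lines. Cyfip2, a regulator of actin assembly, had the highest log2 fold change, from 76.5 ± 4.52 in wild type to 18270 ± 588 in knockout (SD, n = 3 each, log2 7.63). The secreted protease Htra1 rose by 6.41, the lysosomal protease Ctsc by 6.38, the neuronal adhesion gene Nrcam by 6.37, the neuronal microtubule gene Map2 by 6.04 and the acyltransferase Mboat2 by 5.96. The cytochrome P450 gene Cyp2f2 had the lowest, from 8355 ± 171 to 32.9 ± 4.53 (SD, n = 3 each, log2 -7.42). The matrix proteoglycan Aspn had a log2 fold change of -7.38, and the interferon-induced genes Rtp4, Iigp1, Usp18 and Sp100 had values of -7.02, -6.98, -6.94 and -6.91. These 12 genes had adjusted p-values of 1.42e-13 or less, and their arrays of the 2 genotypes did not overlap. The size and order of such folds depend on the offset added before taking logs, and with an offset of 1 the value of Aspn was lower than that of Cyp2f2.

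All 33 tested genes of the interferon-stimulated list were lower in knockout at 18 h, and all 33 were lower at 30 h (list test adjusted p = 1.24e-23 and 3.58e-29). With an estimated correlation the list adjusted p was 0.0325 at 18 h and 0.0163 at 30 h. Ifit1 went from 9357 ± 736 to 77.3 ± 15.4 at 18 h (SD, n = 3 each). In the HOXA cluster 8 of 9 tested genes were lower at each time, with Hoxa10 at -3.47 at 18 h. The HOXA list had adjusted p = 0.000791 at 18 h and 0.00231 at 30 h, and adjusted p = 0.21 and 0.218 with an estimated correlation. All 6 tested HOXC genes were lower at both times, among them Hoxc8, from 4962 ± 269 to 50.2 ± 14.3 at 18 h (SD, n = 3 each), and Hoxc10 at -4.94. The HOXC list had adjusted p = 1.83e-05 at 18 h and 2.36e-05 at 30 h, and adjusted p = 0.143 and 0.129 with an estimated correlation. In the HOXB cluster 6 of 9 genes were lower at 18 h, led by Hoxb6 at -4.30 (list adjusted p = 0.0233, and adjusted p = 0.267 with an estimated correlation). The 4 tested HOXD genes did not move as a list at 18 h (adjusted p = 0.632), and Hoxd9 was higher by 0.65. For these 5 lists at 18 h, the counts adjusted over the list alone were the same as those over all genes.

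Genes of mitosis were higher in knockout at 18 h in 36 of 38 cases and lower in 1, with Cdca8, a subunit of the chromosomal passenger complex, at 1.73 (list adjusted p = 1.08e-10, and adjusted p = 0.312 with an estimated correlation). At 30 h 32 were higher and 1 lower (list adjusted p = 1.55e-08, and adjusted p = 0.448 with an estimated correlation). Of 26 glycolysis and hypoxia genes 20 were higher and 4 lower at 18 h, with the lactate transporter Slc16a3 at 4.31 (list adjusted p = 7.29e-06, and adjusted p = 0.199 with an estimated correlation). Of 17 genes responsive to TGF-beta or to the YAP and SRF factors, 11 were higher and 3 lower at 18 h, with Ccn2 at 3.48 and Ankrd1 at 3.21 (list adjusted p = 0.00106, and adjusted p = 0.0871 with an estimated correlation). Of 21 p53 target and senescence genes 18 were lower and 2 higher at 18 h, with the cell cycle inhibitor Cdkn2b at -3.27 (list adjusted p = 0.00014, and adjusted p = 0.267 with an estimated correlation). Of 19 adipocyte markers 14 were lower and 2 higher at 18 h, with Cd36 at -6.05 and Fabp4 at -4.98 (list adjusted p = 0.00047, and adjusted p = 0.143 with an estimated correlation). Adjusted over the list alone, the 18 h counts of these 5 lists did not change.

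Matrix genes changed in both directions, and the list was not called at 18 h (adjusted p = 0.345, list median 0.127 and mean -0.0521). Of its 38 tested members 19 were higher, such as Tnc at 5.58, and 12 were lower, such as the collagen VI gene Col6a2, from 9883 ± 767 in wild type to 348.5 ± 50.7 in knockout (SD, n = 3 each). These counts were the same adjusted over the list alone. At 30 h 12 were higher and 17 lower, with 18 lower adjusted over the list alone, and the list was not called (adjusted p = 0.414). Among markers of other cell types, Nes and Map2 were 2 of 4 neural and glial markers that were higher, of 10 tested, at both times (list adjusted p = 0.0156 at 18 h and 0.00379 at 30 h, and adjusted p = 0.308 and 0.218 with an estimated correlation). Of 12 macrophage and blood cell markers 2 were higher and 2 lower at each time (list adjusted p = 0.909 at 18 h and 0.871 at 30 h). Of 5 pericyte markers 4 were lower and 1 higher at each time, with Angpt1 at -6.81 at 18 h, and the list was not called at 18 h (adjusted p = 0.0705) and was called lower at 30 h (adjusted p = 0.018, and adjusted p = 0.218 with an estimated correlation). Of 12 fibroblast core markers 7 were lower and 3 higher at 18 h (list adjusted p = 0.241) and 8 lower and 4 higher at 30 h (list adjusted p = 0.0803), and Pdgfra was among the lower, with 3811 ± 212 in wild type and 395.4 ± 42.9 in knockout at 18 h (SD, n = 3 each). The counts for these 4 marker lists were the same adjusted over the list alone.

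In all, 8384 of 13956 genes differed at 18 h, 3672 higher and 4712 lower in knockout, and 2014 of these by at least 2-fold. The share higher was 43.8%, and it was 50.5% under quantile scaling, 50.3% after array medians were set equal and 48.4% under cyclic loess, so the balance of directions depends on the scaling. The arrays of the 2 genotypes did not overlap in 63.1% of genes, where chance gives 10%.

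At 30 h Cyfip2, Nrcam, Ctsc and Mboat2 were again among the highest log2 fold changes, and Aspn, Cyp2f2, Sp100 and Usp18 among the lowest. Cyfip2 had a log2 fold change of 6.76, Nrcam 6.36, the matrix protease Mmp10 5.98, Ctsc 5.97, the intermediate filament gene Nes 5.84 and Mboat2 5.65. Aspn had a value of -7.04, the calcification inhibitor Mgp -6.71, Cyp2f2 -6.71, Sp100 -6.55 and the interleukin 1 antagonist Il1rn -6.55. Usp18 went from 9944 ± 358 to 64.4 ± 25.1 and Il1rn from 5985 ± 313 in wild type to 49.0 ± 12.8 in knockout (SD, n = 3 each). Cholesterol biosynthesis genes, of which 14 of 20 were higher and 1 lower at 18 h (list adjusted p = 0.0015, and adjusted p = 0.234 with an estimated correlation), were higher in 3 and lower in 9 at 30 h (list adjusted p = 0.303). Of 21 p53 target and senescence genes 20 were lower at 30 h (list adjusted p = 3.3e-08, and adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone, the counts for these lists were the same.

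At 30 h 7382 genes differed, 3390 higher and 3992 lower in knockout, 1534 of them by at least 2-fold. Arrays did not overlap in 61.5% of genes, where chance gives 10%. The 2 times shared 2634 genes higher in both, where independent lists would share 892, and 3260 lower in both, where independent lists would share 1348. Another 187 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes at the 2 times correlated at r = 0.931. Averaged over both times 9097 genes differed, 4099 higher and 4998 lower, a share higher of 45.1% that became 50.9% under quantile scaling.

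**Figure D2:**
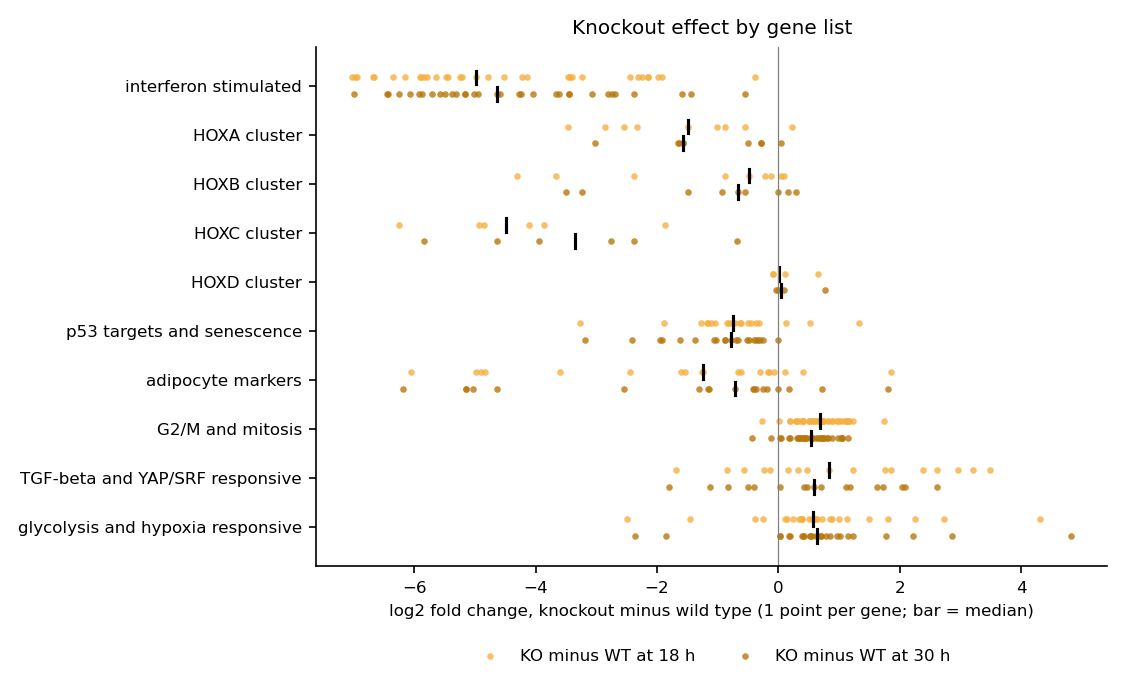
Log2 fold change, knockout minus wild type (x axis), of the tested genes of 10 gene lists (y axis), 1 point per gene, with 18 h and 30 h in different colours and a black bar at each median. All 33 interferon-stimulated genes lie left of 0 at both times, with medians of -4.99 and -4.64.

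In wild type several clock genes, among them Per2, Per3 and Dbp, fell between 18 h and 30 h, and the activator Arntl rose. Per3 fell by 1.07 on the log2 scale, Dbp by 1.00, Per2 by 0.92, Tef by 0.75 and Bhlhe41 by 0.61, while Arntl, which encodes BMAL1, rose by 0.73. Dbp, an output transcription factor driven by the E-box, had an intensity of 1049 ± 86.5 at 18 h and 515.2 ± 24.5 at 30 h (SD, n = 3 each). Bhlhe40 fell by 0.53, Cry2 by 0.49, Rora by 0.45 and Nr1d2 by 0.41. Fbxl21 had a value of -0.44 with adjusted p = 0.0525, which passed without wild-type 18 h replicate 3 (-0.59, adjusted p = 0.00886) and, at -0.44, without knockout 18 h replicate 1 (adjusted p = 0.0323) or 3 (0.0477) or 30 h replicate 1 (0.0378). Nr1d1 at 0.02, Cry1 at -0.21, Per1 at -0.30, Ciart at -0.27 and Nfil3 at 0.10 did not pass. The calls of Rora and Nr1d2 ended without wild-type 18 h replicate 1 or 2 or 30 h replicate 1 or 3, with values of -0.41, -0.42, -0.40 and -0.46 for Rora and -0.39, -0.38, -0.42 and -0.37 for Nr1d2. The call of Cry2 ended without wild-type 18 h replicate 2 (-0.44) or 30 h replicate 1 (-0.43). Of 18 core clock genes 7 fell and 1 rose (list adjusted p = 4.15e-05, and adjusted p = 0.226 with an estimated correlation), with 9 fallen and 1 risen adjusted over the list alone. Of 19 genes with E-box driven rhythms 8 fell and 0 rose, with 12 fallen and 1 risen adjusted over the list alone (list adjusted p = 1.78e-10, and 0.0305 with an estimated correlation).

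DNA replication and the contractile gene Acta2 rose with time in wild type. Acta2, smooth muscle actin, rose from 1163 ± 213 to 5182 ± 780 (SD, n = 3 each, log2 2.14). Sh2d1b1 rose by 1.00, the integrin ligand Npnt by 0.93, the receptor gene Tnfrsf12a by 0.92, Serpinb9e by 0.85 and Id2 by 0.77. The enzyme gene Ggt5 had a value of -1.15, Ndrg2 of -1.01 and Sorbs2 of -0.95. Of 35 genes of G1/S and DNA replication 28 rose and 0 fell, with Mcm5 at 0.71 and Cdc6 at 0.68, and 32 rose adjusted over the list alone (list adjusted p = 1.53e-36, and 0.0305 with an estimated correlation). Of 26 glycolysis and hypoxia genes 6 fell and 0 rose, with Egln3 at -0.66, and 15 fell adjusted over the list alone (list adjusted p = 3.7e-10, and adjusted p = 0.107 with an estimated correlation). Of 16 heat shock genes 4 rose, and 8 adjusted over the list alone (list adjusted p = 1.08e-05, and adjusted p = 0.16 with an estimated correlation). Of 25 unfolded protein response genes 5 rose, Chac1 by 0.77, and 11 adjusted over the list alone (list adjusted p = 2.12e-05, and adjusted p = 0.349 with an estimated correlation).

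In all 553 genes changed with time in wild type, 337 higher and 216 lower at 30 h, 6 of them by at least 2-fold, 2 higher and 4 lower. The share of calls that were higher was 60.9%, and 81.0% after the array medians were set equal. Without wild-type 30 h replicate 3 the balance turned, with 74 higher and 83 lower (47.1%). Arrays did not overlap in 25.6% of genes, where chance gives 10%. The count was 254, 178 and 907 without wild-type 18 h replicate 1, 2 or 3, 164, 316 and 157 without wild-type 30 h replicate 1, 2 or 3, and 1032 without knockout 18 h replicate 1.

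**Figure D3:**
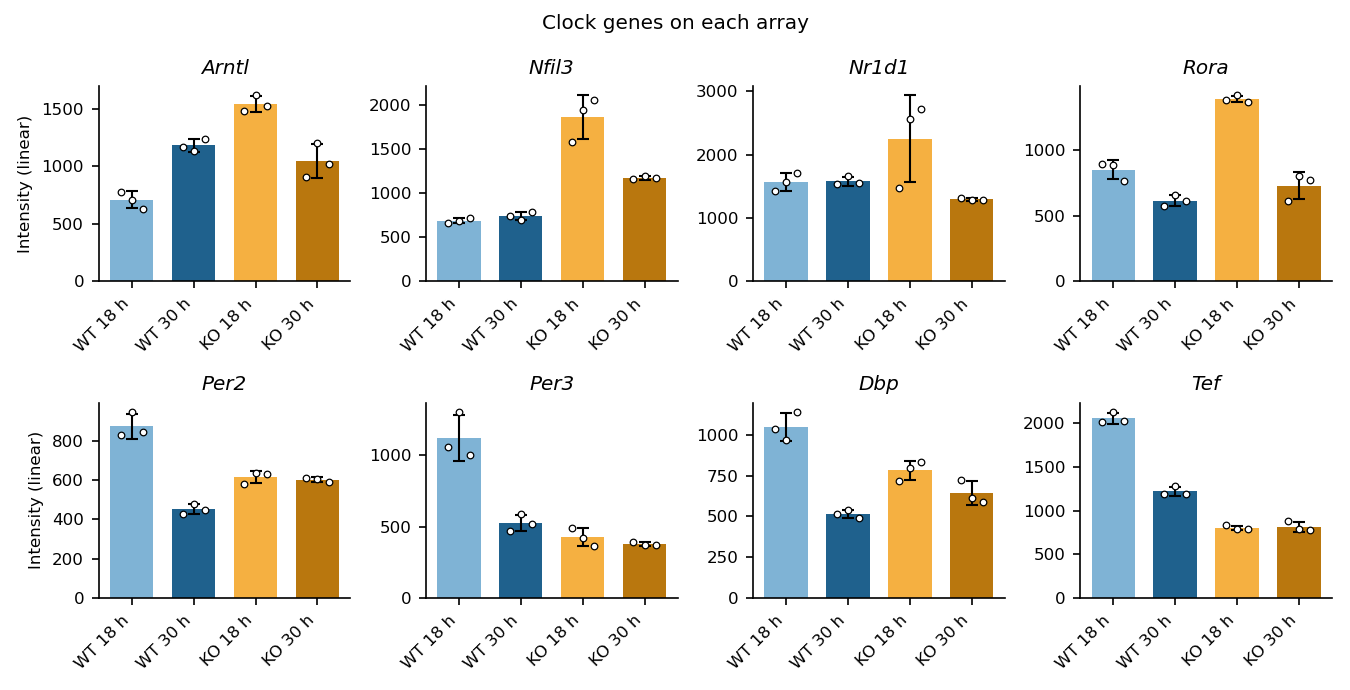
Intensity on a linear scale (y axis) of 8 clock genes, 1 panel per gene, in the 4 groups of genotype and hours after serum shock (x axis), with bars for the group mean, error bars for the SD (n = 3) and points for single arrays. Per3 and Dbp fall between the times in wild type, and Arntl rises in wild type and falls in knockout.

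In knockout Prl2c5, Spag1 and Samd9l were among the largest rises between the times, and Tnfsf18 and Txnip among the largest falls. Prl2c5, a placental prolactin family gene whose probes may also read its close relatives, rose from 44.3 ± 10.5 to 425.4 ± 64 (SD, n = 3 each, log2 2.87). Spag1 rose by 1.96, Samd9l by 1.91, Ppbp by 1.79, the receptor gene Gpr149 by 1.75 and Cxcl5 by 1.73. Ppbp and Cxcl5 encode chemokines, but of 21 inflammatory cytokine and chemokine genes 5 rose and 11 fell, with 6 risen and 11 fallen adjusted over the list alone, and the list was not called (median -0.267, list adjusted p = 0.277). The cytokine gene Tnfsf18 had 2858 ± 1182 at 18 h and 226.3 ± 19.5 at 30 h (SD, n = 3 each, log2 -3.47). Txnip, an inhibitor of thioredoxin and glucose uptake, had a value of -2.94, Car6 -2.33, Serpinb1a -2.29, Gadd45a -2.04 and Nos2 -1.93. A position was taken over 427 genes that part knockout replicates 2 and 3 at 18 h from the 30 h arrays. With genes weighted by the squared size of their change, replicate 1 of 18 h lay 0.378 of the way to 30 h.

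Of the clock genes in knockout, Rora fell by 0.93, Bhlhe41 by 0.86, Nr1d1 by 0.74, Cry2 by 0.69, Per1 by 0.65, Nfil3 by 0.65, Csnk1e by 0.60 and Arntl by 0.56, and Ciart rose by 0.51. Per2 at -0.03, Per3 at -0.16, Tef at 0.02, Nr1d2 at 0.06 and Bhlhe40 at -0.05 did not pass. Fbxl21 fell by 0.47, Dbp by 0.28 and Cry1 by 0.27, and Timeless rose by 0.25 and Csnk1d by 0.19. The Dbp call ended without knockout 18 h replicate 2 (-0.27) or 3 (-0.23) and without 30 h replicate 2 (-0.25) or 3 (-0.22), and the Cry1 call without 18 h replicate 2 (-0.25) or 3 (-0.23) or 30 h replicate 1 (-0.24). The Timeless call ended without knockout 18 h replicate 2 (0.19) or 3 (0.20), knockout 30 h replicate 1 (0.23) or 2 (0.24), or wild-type 18 h replicate 1 or 2 or 30 h replicate 1, 2 or 3 (0.25 each), and under all 3 scalings tried, at 0.21 to 0.23. The Csnk1d call ended without knockout 18 h replicate 2 (0.17) or 3 (0.17) or 30 h replicate 1 (0.17) or 2 (0.16), and under 2 of the 3 scalings. Of 18 core clock genes 9 fell and 3 rose, also adjusted over the list alone (list adjusted p = 0.0304, and adjusted p = 0.619 with an estimated correlation), and the call ended without knockout 30 h replicate 3 (list shift -0.198, adjusted p = 0.0724).

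Cholesterol biosynthesis fell with time in knockout, in 14 of 20 genes with 1 risen, among them Insig1 at -1.08 and Lss at -0.80 (list adjusted p = 9.15e-06, and adjusted p = 0.193 with an estimated correlation). Matrix genes fell in 19 of 38 cases with 1 risen (list adjusted p = 5.63e-05, and adjusted p = 0.604 with an estimated correlation). Immediate early serum response genes fell in 14 of 28 cases with 4 risen, such as Egr1 at -1.15 (list adjusted p = 0.00489, and adjusted p = 0.777 with an estimated correlation). Heat shock genes rose in 10 of 16 cases with 0 fallen, such as Hsph1 at 1.25 (list adjusted p = 0.00124, and adjusted p = 0.557 with an estimated correlation). Of the 6 HOXC genes tested 4 rose (list adjusted p = 0.0239, and adjusted p = 0.604 with an estimated correlation). Among them Hoxc5 rose by 1.29, from 91.3 ± 50.7 to 230.7 ± 24.4 (SD, n = 3 each). The knockout means of Hoxc5 and Hoxc8 at 18 h lay under the filter intensity of 175. The list result thus rests in part on dim values. Adjusted over the list alone, 15 serum response genes fell, 11 heat shock genes rose and the other counts were the same.

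In all 5484 genes changed with time in knockout, 2912 higher and 2572 lower at 30 h, 266 of them by at least 2-fold, 124 higher and 142 lower. The share higher was 53.1%, and it was 48.7% under quantile scaling, 49.0% after array medians were set equal and 44.1% under cyclic loess. Without knockout 18 h replicate 1, which stands apart from the other 18 h arrays, the count was 5992. Arrays did not overlap in 46.2% of genes, where chance gives 10%. Across genes, which are not independent replicates, the time effects in the 2 genotypes correlated at r = 0.28. They shared 149 genes higher in both, where independent lists would share 70.3, and 124 lower in both, where independent lists would share 39.8. Another 64 were called in opposite directions.

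The time effect differed between genotypes for single clock genes, in both directions, and for genes of cholesterol synthesis. Of 18 core clock genes 5 had a higher and 4 a lower time effect in knockout, and the list was not called (adjusted p = 0.815). Of 19 genes with E-box driven rhythms 8 were higher and 3 lower, and the list was not called (adjusted p = 0.463, median -0.0583, mean 0.135, test direction up). Both counts were the same adjusted over the list alone. The difference was -1.29 for Arntl, which rose in wild type and fell in knockout, 0.91 for Per3, 0.89 for Per2, 0.78 for Ciart, 0.77 for Tef and 0.72 for Dbp, all on the log2 scale as knockout minus wild type. Nfil3 had -0.75, Csnk1e -0.57, Bhlhe40 0.48 and Nr1d2 0.47. Nr1d1 had -0.76 (adjusted p = 0.0254), a call that ended without wild-type 18 h replicate 1 (-0.69), wild-type 30 h replicate 2 (-0.72), knockout 18 h replicate 2 (-0.64) or 3 (-0.60) or knockout 30 h replicate 2 (-0.75). Rora had -0.47 (adjusted p = 0.0296), a call that ended without wild-type 18 h replicate 3 (-0.40), wild-type 30 h replicate 2 (-0.42) or 3 (-0.47), knockout 18 h replicate 2 (-0.46) or knockout 30 h replicate 1 (-0.35). Per1 had -0.35 (adjusted p = 0.117) and passed without knockout 18 h replicate 1 (-0.47, adjusted p = 0.0133), and Bhlhe41, Cry1, Cry2, Hlf and Clock did not pass. Kmt2a had -0.38 (adjusted p = 0.0653) and passed without wild-type 18 h replicate 2 (-0.50) or knockout 30 h replicate 3 (-0.45), or after array medians were set equal (-0.47).

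The largest differences in the time effect were Prl2c5 at 2.21, Spag1 at 1.96, Samd9l at 1.93, Ppbp at 1.85, Gpr149 at 1.78 and Macc1 at 1.76, and on the other side Tnfsf18 at -3.61, Txnip at -2.68, Serpinb1a at -2.42, Gadd45a at -2.38, Kctd16 at -1.94 and the glycolytic gene Aldoc at -1.87. Of 20 cholesterol genes 14 had a lower time effect in knockout and 0 a higher time effect, with 15 lower adjusted over the list alone (list adjusted p = 2.44e-10, and 0.0395 with an estimated correlation). Of 17 TGF-beta and YAP or SRF responsive genes 7 were lower, as with Ccn2 at -1.86, and 7 lower and 1 higher adjusted over the list alone (list adjusted p = 0.000278, and 0.0395 with an estimated correlation). Of 35 replication genes 21 were lower, with 22 lower and 2 higher adjusted over the list alone (list adjusted p = 2.81e-11, and adjusted p = 0.244 with an estimated correlation). Of 6 RORE driven clock genes 4 were lower, also adjusted over the list alone (list adjusted p = 0.00201, and adjusted p = 0.244 with an estimated correlation). In all the difference passed for 2838 genes, 1427 higher and 1411 lower in knockout, 243 by at least 2-fold. The share of calls that were higher was 50.3%, and it was 42.6% under quantile scaling, 30.1% after array medians were set equal, 37.4% after cyclic loess and 44.0% without wild-type 30 h replicate 1, so neither direction held a stable majority.

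Of the 553 genes that changed with time in wild type, 234 also had a called difference between genotypes. In 181 of these the time effect was smaller or opposite in knockout and in 53 it was larger, where the choice of genes on the wild-type value favours the former. A further choice took 4702 genes on the time effect averaged over both genotypes, which favours neither only where both vary alike between replicates. The median replicate SD was 0.101 and 0.0814 in wild type at 18 h and 30 h, and 0.106 and 0.0999 in knockout. Of these 4702 genes 86.5% had a larger and 13.5% a smaller time effect in knockout, against 31.9% with a smaller one over all 13956 genes. The median time effect, in the direction of the average, was 0.143 in wild type and 0.428 in knockout (log2). The rotation test of limma (fry) of the difference over these genes, not an exact test of arrays, gave p = 0.00023, with 13.5% of genes smaller in knockout, and 20.4% without wild-type 18 h replicate 3.

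**Figure D4:**
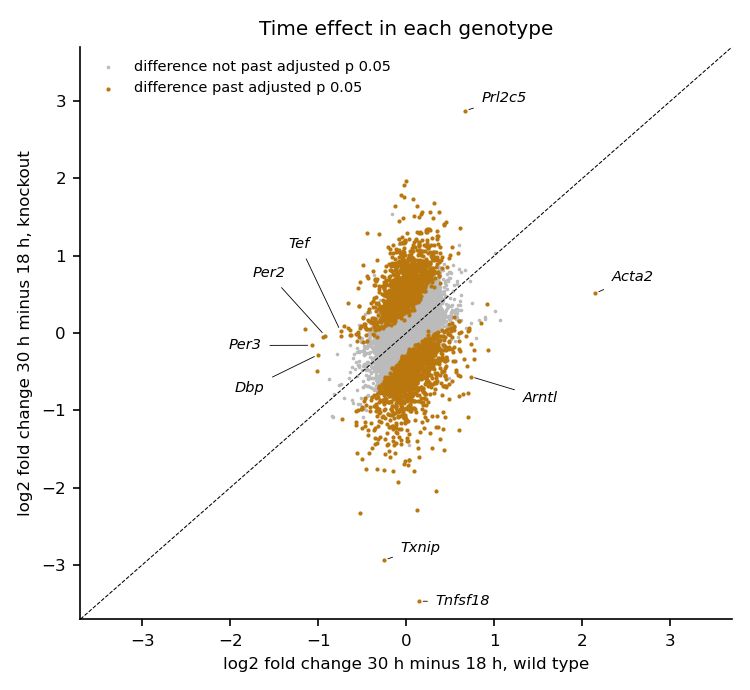
Log2 fold change from 18 h to 30 h in wild type (x axis) and knockout (y axis), 1 point per gene, with genes whose difference between genotypes passed coloured. The dashed line marks equal effects, and Per2, Per3 and Dbp lie left of the centre while Txnip and Tnfsf18 lie far below it.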

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

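The test of a wrong time label for knockout 18 h replicate 1, that of blood cells among the wild-type cells and the gene-by-gene array weights were chosen only after the results had been seen. The time effect differed between genotypes for 2838 genes, and 86.5% of time-changing genes had a larger time effect in knockout. A smaller one was found in 13.5% of these genes, against 31.9% of all tested genes. Each value of the next sentences is the difference of the time effects, knockout minus wild type, on the log2 scale. Among clock genes it was -1.29 for Arntl, 0.48 for Bhlhe40, 0.78 for Ciart, -0.57 for Csnk1e, 0.72 for Dbp, -0.75 for Nfil3, 0.47 for Nr1d2, 0.89 for Per2, 0.91 for Per3 and 0.77 for Tef. It was -0.76 for Nr1d1, a call that ended without wild-type 18 h replicate 1 (-0.69), wild-type 30 h replicate 2 (-0.72), knockout 18 h replicate 2 (-0.64) or 3 (-0.60) or knockout 30 h replicate 2 (-0.75). It was -0.47 for Rora, a call that ended without wild-type 18 h replicate 3 (-0.40), wild-type 30 h replicate 2 (-0.42) or 3 (-0.47), knockout 18 h replicate 2 (-0.46) or knockout 30 h replicate 1 (-0.35). The 2 times, 12 h apart, do not separate a shift of phase from a change of amplitude. Elsewhere it was -3.61 for Tnfsf18, -2.68 for Txnip, -2.42 for Serpinb1a, -2.38 for Gadd45a, -1.94 for Kctd16, -1.87 for Aldoc, 2.21 for Prl2c5, 1.96 for Spag1, 1.93 for Samd9l, 1.85 for Ppbp, 1.78 for Gpr149 and 1.76 for Macc1.

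Of the gene lists, the shift of the same difference against other genes was 0.959 for the HOXC cluster, 0.471 for the HOXA cluster, -0.632 for cholesterol biosynthesis, -0.608 for RORE driven clock genes, -0.406 for DNA replication, -0.374 for serum response, -0.337 for TGF-beta and YAP or SRF responsive genes and -0.21 for matrix genes. With an estimated correlation the adjusted p was 0.263 for HOXC, 0.474 for HOXA, 0.0395 for cholesterol, 0.244 for RORE driven genes, 0.244 for DNA replication, 0.474 for serum response, 0.0395 for TGF-beta and YAP or SRF responsive genes and 0.623 for matrix genes. It was 0.73 for mitosis genes, 0.7 for the unfolded protein response, p53 targets and inflammatory cytokines, and 0.763 for ribosomal proteins. The HOXC shift rests in part on dim values, since the knockout means of Hoxc5 and Hoxc8 at 18 h lay under the filter intensity of 175. The shift was -0.201 for mitosis genes, a call that ended without wild-type 18 h replicate 3 (-0.127), and -0.219 for the unfolded protein response, a call that ended without knockout 18 h replicate 3 (-0.188) or under quantile scaling. It was -0.225 for p53 targets, a call that ended without wild-type 18 h replicate 1 (-0.189), knockout 18 h replicate 3 (-0.181) or knockout 30 h replicate 3 (-0.148), or under quantile scaling or cyclic loess. It was -0.177 for ribosomal proteins, a call that ended without wild-type 18 h replicate 2 (-0.146), knockout 18 h replicate 3 (-0.0816) or knockout 30 h replicate 3 (-0.102). It was -0.276 for inflammatory cytokines, a call that ended without wild-type 18 h replicate 1 (-0.274) or 2 (-0.245), wild-type 30 h replicate 1 (-0.345) or 3 (-0.162), knockout 18 h replicate 3 (-0.258) or knockout 30 h replicate 3 (-0.176), or under each of the 3 scalings tried. Outside the genes tested, 3570 of 12147 probe sets with no symbol listed were called in the averaged knockout effect (29.4%).

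More genes changed with time in knockout than in wild type. An unadjusted p under 0.05 in limma's moderated test was reached by 6421 genes in knockout and 2557 in wild type. The median absolute log2 time effect was 0.177 and 0.0973. For called genes, which depend on the adjusted cutoff, the ratio was larger, at 9.92. The lowest ratio was 8.86 over 3 scalings, and with 1 array left out it ran from 5.81 without knockout 18 h replicate 1 to 33.7 without wild-type 30 h replicate 3, with 21.2, 30.7 and 6.18 without wild-type 18 h replicate 1, 2 or 3 and 32.3 and 16.7 without wild-type 30 h replicate 1 or 2, and it was 4.90 with only the arrays of the groups compared, 5.01 with array weights, 4.65 with gene-by-gene weights, 28.6 over all probe sets and 44.3 with a 2-fold change required, so the size of the excess depends on the setting, while neither the scaling nor a single array accounts for the whole of it. With time reassigned within each genotype, 7 of 100 drawn splits gave as many genes with a different time effect as the real 2838, the highest 3857, but all 7 kept the knockout arrays parted by time and with them the knockout time effect, a structure of the samples, while splits with the knockout arrays mixed gave at most 20, so these splits do not settle whether chance can be excluded. With genotype reassigned within each time, 10 of 100, the real one among them, gave a share as far from 50% as the real one, at a distance of 36.5, the highest other being 45.7. By the same rule chance is not excluded for the share. The other splits as far from 50% had 9 to 1193 time-changing genes against 4702 in the real split, too unlike it to settle the question further. A genotype effect on the time course may still be the source, a hypothesis found and tested on the same data.

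Knockout 18 h replicate 1 lay apart from replicates 2 and 3. Over 427 genes, weighted by the squared size of their change, its position was 0.378 of the way to the 30 h knockout arrays. The quartiles of the single-gene positions were 0.246 and 0.535, which argues against a 30 h sample under a wrong label. A true time between 18 h and 30 h would also give a middle position and is not covered. A mixture with 41% of the 30 h profile brought its median deviation from 0.484 to 0.16, within the 0.106 to 0.164 of the other replicate pairs. This is consistent with part of its RNA coming from 30 h cells, and cells at an intermediate stage would look alike, which was not tested.

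All 33 interferon-stimulated genes tested were lower in knockout. The same 33 were called lower under each of 3 scalings. In the averaged knockout effect the quantile, median and cyclic loess scalings moved the median of all genes by 0.035, 0.018 and 0.0098. The median of the interferon-stimulated genes, without the filter, was -4.87. The outcome was thus nearly certain in advance, and the check shows only that rescaling of that size does not produce the difference. The 23 blood cell markers on the array had a median averaged log2 knockout effect of 0.0273 (quartiles -0.0227 and 0.0936), with 2 called lower and 2 higher. Most were dim in wild type (median intensity 170). Ptprc had 156.8 in wild type and 153.7 in knockout, Tyrobp 183 and 180.4, and Lyz2 69.1 and 66.4, so these markers showed no excess in wild type. Values so near the floor cannot exclude a small share of such cells. Of the brighter ones Cd53, with 5234 in wild type and 760.7 in knockout, and Mpeg1, with 853.7 and 34.1, were lower, Cd34 was higher, and Cd68, with 1054 and 1555, Itgam, with 283.2 and 283.8, and Fcer1g, with 243.8 and 240.9, were not called, so blood cells among the wild-type cells stay open. A difference in interferon signalling between the cells may underlie it, as a hypothesis, and whether it follows from the targeted gene or from the history of the cells was not tested, since the labels name no separate lines.

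For single comparisons, 10 splits of 6 arrays are too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as large a count. The real and highest other counts were 8384 and 0 for knockout at 18 h, 7382 and 0 at 30 h, 553 and 1 for time in wild type, and 5484 and 1 for time in knockout. For the averaged knockout effect 1 of 100 drawn splits, the real one with 9097, gave as many genes, the highest other being 5164. For knockout at each time, every other split put both genotypes into a group. The component that separated the genotypes held 86.8% of the variance, so low counts there were nearly certain in advance. The splits show only that a random allotment of these arrays seldom gives such a count. The splits do not exclude chance differences between cultures, since the replicates may be technical.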

How the results depend on the processing

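Gene-by-gene array weights were the alternative chosen only after the data were seen. A 2-fold change required in addition lowered the counts to 2014 for knockout at 18 h, 1534 at 30 h, 1639 averaged, 6 for time in wild type, 266 for time in knockout and 243 for the difference of time effects, as its construction implies. Array weights, whose estimation stopped before it converged, gave 1742 genes for time in wild type, 8722 for time in knockout and 5844 for the difference, and reversed Nr1d2 for time in knockout to -0.13 (adjusted p = 0.0477). Gene-by-gene weights gave 1623 genes for time in wild type and 5137 for the difference. Time in wild type called 997 genes with only the arrays of the groups compared and 244 probe sets among all probe sets. The cause of these changes was not tested. Of 83 list calls, 7 were made with an estimated correlation, and fry, which compares no list with other genes, made 136.

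With each array left out in turn, knockout called 7718 to 8507 genes at 18 h, 6551 to 7802 at 30 h and 8669 to 9241 averaged, and time in knockout 4278 to 5992. Time in wild type called 157 to 1032, with 254, 178 and 907 without wild-type 18 h replicate 1, 2 or 3, 164, 316 and 157 without 30 h replicate 1, 2 or 3, and 1032 without knockout 18 h replicate 1. The difference of time effects ran from 1895 to 4145, the share of genes with a smaller time effect in knockout from 11.4% to 20.4% (the highest without wild-type 18 h replicate 3), the list calls from 78 to 89, Kmt2a at 30 h from -0.64 to -0.52 and the named gene calls from 676 to 724. Of 760 results of named genes, 663 kept direction and side of the threshold under all alternatives that gave a value, 89 lost a call under some, 7 gained one and 1 reversed. Of 94 list results 9 kept theirs, 76 lost a call under some, all 76 with an estimated correlation, and 9 gained one. Dim genes near the filter of 175 limit what can be measured.

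The replicate numbers did not pair the arrays. Of 18 pairs with the same number 4 had deviations correlated over 0.1, with a range of -0.46 to 0.45, and in 7 of the pairs the correlation was highest with the own number. With the replicate number as a block the counts were 8262, 7251, 8986, 485, 5375 and 2725 for the 6 comparisons in the order of the 2-fold counts, the share was 13.3%, the list calls 82, Kmt2a at 30 h -0.57 and the named gene calls 721. The block ended 6 named gene calls and 2 list calls, and moved no count by over 1.5 times.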

Other observations

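The test of genes next to Kmt2a was written before its result was seen, and the genes in the next 2 sentences were taken from the gene lists, fitted without the filter, after their values were seen. At 18 h several genes bright in a single genotype fell under the filter because their mean over all arrays was low. Postn, a matrix protein, had 939.8 ± 77.2 in wild type and 22.7 ± 12.1 in knockout (SD, n = 3 each, log2 -4.67), Mx1, an antiviral gene, had a log2 fold change of -5.07 and Hoxc13 of -2.90. On the other side Hoxd8 went from 32.9 ± 7.21 to 353.8 ± 64.2 (log2 2.92), and Pmaip1, a pro-apoptotic p53 target, from 57.0 ± 14.4 to 853.6 ± 331 (log2 3.51), both SD with n = 3 each.

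Imprinted genes, which are expressed from a single parental allele, went both ways at 18 h, with 4 of 20 higher, 6 lower and a list adjusted p = 0.909, also adjusted over the list alone. Ndn was lower by a log2 difference of -2.77 and Peg10 of -2.26, and Peg3 was higher, with 270.4 ± 67.1 in wild type and 1070 ± 169 in knockout (SD, n = 3 each, log2 1.94). Of 21 NRF2 and glutathione genes 15 were lower and 3 higher at 18 h, with 15 and 4 adjusted over the list alone (list adjusted p = 0.00547, and adjusted p = 0.383 with an estimated correlation). Of 35 ribosomal protein genes 26 were higher and 0 lower at 18 h, also adjusted over the list alone (list adjusted p = 4.5e-05, and adjusted p = 0.616 with an estimated correlation).

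A segment of chromosome carried along with the targeted locus was a hypothesis for some of the knockout differences. Among the 50 nearest tested genes on each side of Kmt2a, 62% were called, and 68.2% of 11940 such windows along the genome had as high a share. This argues only against a large excess of called genes there. The median window already had 65% called, and the top 5% of windows started at 76%. A segment that changed a few genes would not have stood out.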
